A study of Mus musculus with 2 samples.

How the data were processed

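Droplet RNA libraries were made from the right ventricle of mouse pups with loxP-flanked alleles of Ep300 (p300) and Crebbp (CBP), which encode related lysine acetyltransferases. The genotype label also names a floxed Trap allele and says nothing more about it. Per the labels' protocols, AAV9, an adeno-associated virus used for delivery to the heart, was injected within a day of birth, and tissue was taken on postnatal day 21. The labels give both libraries the same genotype, treatment and ages, so they form 1 group of 2 samples with no control sample. No comparison of knockout with control was possible, and nothing in the labels says which animals, or how many, went into each library. With library as a block, the p-values below measure how differences between classes vary between these 2 libraries, pooled over the classes in the fit, and part of that may be technical. Barcodes ending in 1 and 2 were assigned to the samples whose titles end in 1 and 2, called library 1 and library 2 here. Per the labels' protocols, frozen tissue was digested with collagenase, CD45-positive cells were enriched with magnetic beads, and libraries used 3' v3 chemistry.

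The deposited values are raw UMI counts per gene and barcode, not normalized, written by Cell Ranger 6.0.0 per the file headers. The submitters' processing notes name fastp, Trimmomatic, Cell Ranger, Seurat and edgeR and the genome build GRCm38 (mm10), without saying what each was used for. The table has 27999 features, of which the last is named GFP, and 22183 barcodes. Of the features, 4021 had no count and 121 shared their symbol with another feature. No file with the authors' cell annotation was used here. The counts per gene give no read positions, and 3' reads may lie outside the deleted exons. With no control sample either, a level of Ep300 or Crebbp RNA shows nothing about a deletion. Whether reads were assigned with strand, and whether intronic reads were counted, is not given in the sources used here. Counts of genes with near-identical copies are uncertain to that extent.

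Everything else was computed from those counts. This used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0, and matplotlib 3.10.9 for plots. Cells needed at least 500 UMIs, 200 detected genes and at most 25% mitochondrial counts, which 22137 barcodes passed. A doublet score was computed per library from simulated doublets, 2 per cell, with a threshold placed by Otsu's method. The score, taken before the mitochondrial limit was applied, marked 700 of the 12736 barcodes of library 1 with enough UMIs and genes (5.50%) and 653 of 9408 such barcodes of library 2 (6.94%), and these cells were removed together with whole clusters of at least 40% marked cells. Of the simulated doublets, 50.6% in library 1 and 57.6% in library 2 lay over the threshold, so doublets may remain among the kept cells. In all, 1721 cells were removed and 20416 kept, 11936 from library 1 and 8480 from library 2. Cells were clustered with the Leiden method at resolution 1 (leidenalg 0.10.2, python-igraph 0.11.9) on 30 principal components of 2000 variable genes and 15 neighbours, with no correction for library. The genes of the 16 lists fixed in advance (284 genes, 5 of them absent from the table) were left out of the clustering features. This gave 29 clusters.

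A cluster was called "X-like" from marker genes of 19 cell types fixed before the data were examined. The scoring rule was set after the data were seen. The best type had the highest mean log2 fold of its markers over the lower quartile of clusters with at least 50 cells, that mean being at least 2-fold, with at least 3 markers 2-fold or more above it and 20 counts each. A cluster stayed unnamed if its 10 leading genes held more markers of another type, if its median UMI count was over 3 times below its library's with no marker among the leading genes, or if it had under 50 cells. Hepatocyte and lymphocyte lists used only to withhold names were written after the data were seen. The 11 unnamed clusters held 11.2% of kept cells of library 1 and 3.74% of library 2. Of these, cluster 7 had 958 cells of library 1 and 35 of library 2, a median of 560 UMIs and cardiomyocyte transcripts.

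Counts were summed per library and class. The 7 classes with at least 50 cells in both libraries gave 14 sums, tested with edgeR 4.0.16 (quasi-likelihood, TMM scaling, filterByExpr, library as a block) in R 4.3.3, with Benjamini-Hochberg adjusted p-values. Residual degrees of freedom were 6 and the biological coefficient of variation was 0.145. The block is paired by construction, since the classes of a library come from the same cell suspension. Each class was compared with the mean of the other classes. A gene was counted as higher or lower at an adjusted p under 0.05 and at least a 2-fold change. List members were called at an adjusted p under 0.05 alone, over all genes and over the list alone. Lists were tested with camera (limma 3.58.1) at the preset correlation of 0.01 and again with an estimated correlation. The test was tested on simulated data. For the comparison of cardiomyocyte-like cells, with 11984 simulated genes, it recovered 82% of 2-fold and 98% of 4-fold changes. It called 5 of 11784 unchanged genes. These calls used an adjusted p under 0.05 alone, without the 2-fold limit. Only 100 genes were changed at each fold, as many up as down. Shifts of scaling and RNA carried between cells were not simulated, so these rates do not cover them.

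TMM scaling raised log2 differences of cardiomyocyte-like cells by 0.45 over the CPM scale (counts over the total of the library and class, times 1e6), as the median of 5141 genes over 20 CPM on both sides. On those genes the median difference was 0.29 with TMM and -0.14 on the CPM scale, so directions of small differences depend on this choice.

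Differences between the libraries were not tested, because the labels put both in 1 group. They are given as both values with exact Poisson or Clopper-Pearson 95% intervals, which cover counting error only. The floor for a count of 0 was 3 counts. A list's median log2 ratio was set against 10000 random lists of the same size matched on mean expression, each member drawn within 100 ranks and draws past the highest gene set to that gene. As a check added after the data were seen, members were also drawn from the 100 genes nearest in expression, or in expression and gene length, without the list's own genes. To compare shares of cells with a UMI across depths, cells were thinned to 1000 UMIs, which left out 1461 shallower cells of library 1 and 205 of library 2.

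Gene names follow a rule fixed before the data were examined. Ep300 and Crebbp were always named, as were the measured calcium handling genes in cardiomyocyte-like cells. From each other list, the 3 members with the largest absolute fold change past the threshold in cardiomyocyte-like cells were named. Between libraries, the 10 genes highest in each library were taken in cardiomyocyte-, endothelial-, fibroblast- and macrophage-like cells, among genes of at least 200 counts and leaving out mitochondrial, ribosomal, haemoglobin and sex-linked genes. GFP, Xist, Y-linked genes, liver transcripts and genes compared within library 2 lie outside the rule and were chosen after their values were seen. Some genes that the rule names are not reported here. Alternatives were size factors of the DESeq2 type, no count filter, DESeq2 1.42.0, no block, other clustering resolutions, kept doublets, other cell filters, list genes kept in clustering, thinning, TMM between libraries and each library left out. Added after the data were seen were a class without its atrial-gene cluster, library 2 restricted to cells with Xist and no Y counts, a contrast of pairs of clusters and a fit with no count filter that kept the scaling factors of the filtered genes. Positions are from GENCODE M21 on GRCm38, counted from 1.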

Results

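The study profiled right ventricular cells of mouse pups after p300/CBP knockout, and its title asks about calcium handling in cardiomyocytes. Raw UMI counts were available for 2 libraries of this 1 group. Library 1 held 12736 barcodes and 57982200 UMIs, with a median of 3586 UMIs and 1798 genes per barcode. Library 2 held 9447 barcodes and 50199793 UMIs, with a median of 3945 UMIs and 2016 genes. Mitochondrial transcripts made up a median of 0.338% of counts in library 1 and 0.229% in library 2.

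The first question was which cells the libraries hold. Cardiomyocyte-like cells, named from marker transcripts, were 66.4% of 11936 kept cells in library 1 (95% Clopper-Pearson interval 65.6 to 67.3) and 27.0% of 8480 in library 2 (26.1 to 28.0). Fibroblast-like cells were 9.39% and 29.2%. Endothelial-like cells were 5.29% and 10.6%, and endocardial-like cells, with Nrg1 and Npr3 among their leading genes, were 0.947% and 11.1%. Epicardial or mesothelial-like cells, with Msln and Upk3b among theirs, were 0.411% and 6.42%. Pericyte-like cells (3.09% and 4.75%), macrophage-like cells (2.04% and 4.15%) and lymphatic endothelial-like cells (0.427% and 2.16%) also took a larger share in library 2. Smooth muscle-like cells (0.469% and 0.259%) and Schwann or glial-like cells (0.285% and 0.625%) were rare in both. With a stricter cell filter the mean share of smooth muscle-like cells was 1.09%, against 0.364%. The mean share of cardiomyocyte-like cells was 46.7% ± 27.9 (SD, n = 2), and that of pericyte-like cells 3.92% ± 1.17.

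**Figure D1:**
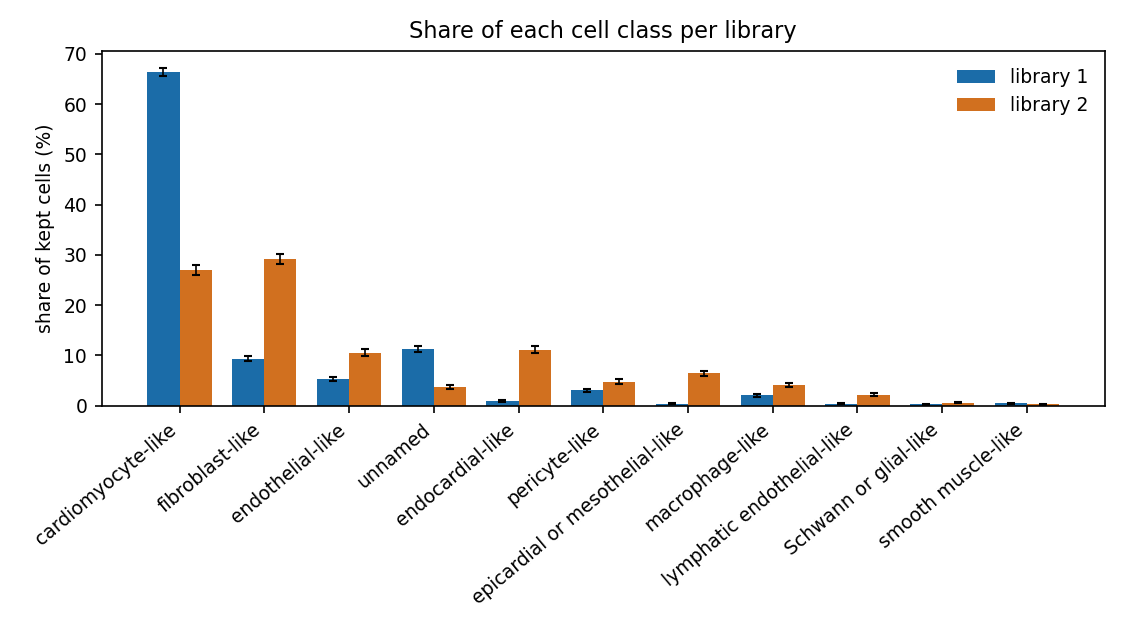
Share of kept cells (%, vertical axis) in each cell class for library 1 and library 2. Bars start at 0 and error bars are 95% Clopper-Pearson intervals. Cardiomyocyte-like cells were 66.4% of library 1 and 27.0% of library 2.

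The protocol names an enrichment of CD45-positive cells, which would bear on these shares. Ptprc, the gene of CD45, had a UMI in 2.63% of all barcodes of library 1 (interval 2.36 to 2.92) and 8.60% of library 2 (8.04 to 9.18). In macrophage-like cells Ptprc had a UMI in 64.8% and 83.8% of cells, at median depths of 1486 and 2609 UMIs. In cardiomyocyte-like cells, which should lack Ptprc, the share was 0.542% and 2.32%, at median depths of 4739 and 7296 UMIs. Few barcodes bore Ptprc, and macrophage-like cells were 2.04% and 4.15% of kept cells beside 66.4% and 27.0% cardiomyocyte-like cells. These values argue against libraries made mostly of CD45-positive cells. Over all barcodes the median mitochondrial share was 0.338% and 0.229%, and the 95th percentile 2.77% and 1.82%. Malat1, a nuclear RNA, was 5.58% and 3.73% of counts. These values argue against whole cells in most barcodes and go with nuclei, although the protocol names cells. The levels may thus be mostly of nuclear RNA, and the shares and levels carry that limit.

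The targeted genes come next. Ep300 (ENSMUSG00000055024) lies on chromosome 15 from 81585351 to 81652077 on the plus strand and has 31 exons in its principal transcript. Crebbp (ENSMUSG00000022521) lies on chromosome 16 from 4081328 to 4213997 on the minus strand, also with 31 exons. Both positions are on GRCm38. Transcripts of both genes were counted in all named classes of both libraries. In cardiomyocyte-like cells Ep300 was at 111 CPM in library 1 (Poisson interval 107 to 114) and 116 CPM in library 2 (112 to 121), a mean of 113 ± 4.18 (SD, n = 2). Crebbp there was at 380 CPM (374 to 385) and 462 CPM (453 to 472), a mean of 421 ± 58.5 (SD, n = 2). Fibroblast-like cells had 145 and 156 CPM of Ep300 and 521 and 591 CPM of Crebbp. Because 3' counts may lie outside the deleted exons and the labels name no control sample, these levels check neither the deletion nor the labels.

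Macrophage-like cells had the highest Ep300 level of the classes, at 270 CPM in library 1 and 292 CPM in library 2. Against the mean of the other classes Ep300 was 0.92 higher on the log2 scale there (SE 0.13, edgeR adjusted p = 3.26e-05). Crebbp in macrophage-like cells, at 488 and 559 CPM, differed by 0.06 (SE 0.12, edgeR adjusted p = 0.761). Crebbp was lower in lymphatic endothelial-like cells by a log2 value of -0.38 (SE 0.13, edgeR adjusted p = 0.0416). That class had 51 and 183 cells. On the CPM scale its mean was 424, beside 421 in cardiomyocyte-like cells, and this call was not recomputed under the alternatives. No other of the 7 classes tested passed the threshold for Ep300 or Crebbp. After thinning to 1000 UMIs, Ep300 had a UMI in 22.5% and 26.6% of macrophage-like cells, 10.7% and 11.2% of cardiomyocyte-like cells and 13.1% and 14.3% of fibroblast-like cells. Without thinning these shares were 33.2% and 51.7%, 41.4% and 54.7%, and 23.9% and 36.2%.

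In cardiomyocyte-like cells the log2 difference from the mean of the other classes was -0.08 for Ep300 (SE 0.12, edgeR adjusted p = 0.609) and 0.21 for Crebbp (SE 0.11, edgeR adjusted p = 0.109). Both lay below the other classes on the CPM scale, Ep300 by -0.40 in library 1 and -0.63 in library 2 and Crebbp by -0.27 and -0.21, since TMM scaling shifts this comparison by 0.45. The Crebbp difference passed the threshold under 4 alternatives given in the closing section, and neither direction is settled.

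**Figure D2:**
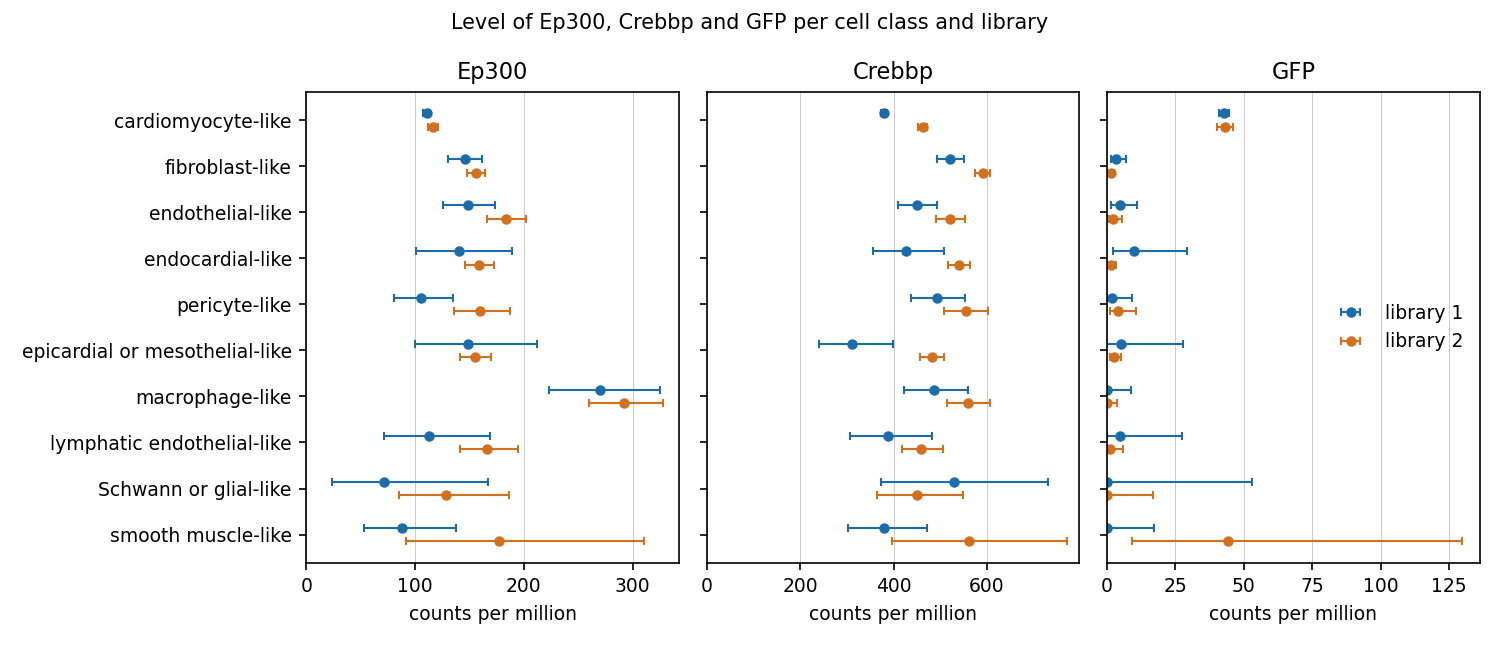
Level of Ep300, Crebbp and GFP (CPM, horizontal axes from 0) in each named class, for library 1 and library 2. Error bars are exact 95% Poisson intervals of counting error. Ep300 was highest in macrophage-like cells (270 and 292), and GFP was at 42.7 and 43.1 in cardiomyocyte-like cells.

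A feature named GFP was present in the table, and its origin is not given in the sources used here. The genotype label names a floxed Trap allele. If that is a reporter with GFP, GFP would mark recombined cells, and if GFP came with the virus it would mark infected cells, and neither was tested. GFP was at 42.7 CPM in cardiomyocyte-like cells of library 1 and 43.1 CPM in library 2, and 17.5% and 22.7% of these cells had a GFP UMI. Over all other named classes together GFP was at 3.54 CPM in library 1 and 1.87 CPM in library 2. That is 8.28% (interval 4.98 to 12.9) and 4.35% (3.08 to 5.97) of the cardiomyocyte-like level. The 12 cardiomyocyte marker transcripts stood in the same classes at 20.9% and 4.53% of their cardiomyocyte-like level. GFP pooled over these classes thus did not exceed the marker share, and background could account for it. In library 1 the marker share lay outside the GFP interval, so the 2 need not share a source. Whether some of these cells carried GFP themselves was not tested. Smooth muscle-like cells of library 2 are an exception left open, with 3 GFP UMIs in 22 cells, or 44.4 CPM (interval 9.15 to 130), beside marker transcripts at 2928 CPM against 50001 CPM in cardiomyocyte-like cells. In fibroblast-like cells, a type compared for background, a GFP UMI was seen in 0.714% and 0.525% of cells at median depths of 1845 and 3079 UMIs. Macrophage-like cells had 0 GFP UMIs, which allows up to 7.24 CPM in library 1 and 2.99 CPM in library 2.

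The main contrast set cardiomyocyte-like cells against the mean of 6 other classes, to describe which genes they carried at a higher level. Of 12399 genes tested, there were 2174 genes higher in cardiomyocyte-like cells than in the mean of the other classes and 2696 genes lower in cardiomyocyte-like cells than in the mean of the other classes (edgeR, adjusted p under 0.05 and at least 2-fold). Without a filter on low counts, which also shifts the scaling, these were 3983 and 2579, and 3294 and 2969 with the scaling kept. Cardiomyocyte transcripts were counted in the other classes and differed between libraries. Marker transcripts were at 7402 CPM in fibroblast-like cells of library 1 and 1960 CPM in library 2. Whether this was free RNA, remaining doublets or debris was not tested.

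Calcium handling genes, the subject of the series title, were mostly higher in cardiomyocyte-like cells. Of 25 tested members 19 were higher and 5 lower, and the same counts were obtained when adjusted over the list alone. Among the higher members, the largest log2 differences were those of Ryr2, the calcium release channel of the sarcoplasmic reticulum, at 4.65 (SE 0.32, edgeR adjusted p = 9.62e-09), and Cacna1c, the pore subunit of the L-type calcium channel, at 4.41. Trdn and Casq2, a scaffold and a calcium buffer of the release complex, were higher by 4.31 and 3.60, and Jph2, which tethers the reticulum to the cell membrane, by 4.14. Atp2a2, the reticulum calcium pump, was higher by 2.98 and its inhibitor Pln by 3.09. Pln is also one of the cardiomyocyte markers used to name the class. Slc8a1, the sodium-calcium exchanger, was higher by 2.81. Srl (3.72), Cacnb2 (3.64), Pde4d (3.61), Hrc (2.75), Sorcs2 (2.72), Cacna2d1 (2.62), Asph (2.08), Camk2d (1.71), Prkaca (1.21) and S100a1 (0.78) were also higher. The S100a1 call was lost with no replicate block (adjusted p = 0.209), and on the CPM scale S100a1 stood at -0.16 in library 1 and 0.70 in library 2. In library 1 alone, S100a1 was at 0.30 and Pln at 1.98. Sln, an inhibitor of the same pump that is abundant in atrial muscle, was higher by 1.34. Without the cluster led by atrial genes its value was -0.56, a loss of the call. The Sln call was also lost with no replicate block, with DESeq2 and with the stricter cell filter, and Sln stood at 0.20 in library 2 alone.

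Members at a lower level included Atp2b4 (-4.83) and Atp2b1 (-1.03), calcium pumps of the cell membrane, and Calm3 (-1.46) and Calm2 (-0.50). The Calm2 call was lost with no filter on low counts and at resolution 0.5. Itpr2, an inositol trisphosphate receptor, stood at -0.28 (edgeR adjusted p = 0.0813), and passed as lower at resolution 2 and with the stricter cell filter. The list's median was 2.72 and its camera adjusted p was 0.00013, against an adjusted p = 0.298 with an estimated correlation of 0.372. The median was 1.78 with doublets kept. It was 3.07 in library 2 alone and 1.98 in library 1 alone.

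These genes have the following positions on GRCm38. Ryr2 is on chromosome 13 from 11553102 to 12106945, Cacna1c on chromosome 6 from 118587240 to 119196418 and Slc8a1 on chromosome 17 from 81373105 to 81738377. Pln is on chromosome 10 from 53337667 to 53345987, and Atp2a2 on chromosome 5 from 122453513 to 122502225.

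Contractile and metabolic genes were also higher in cardiomyocyte-like cells. Sarcomere genes were higher in 23 of 24 tested, led by Myh7 (5.57), Ttn (5.43) and Ldb3 (4.75), and this list shares genes with the cell type markers and is no independent evidence. All 19 fatty acid oxidation genes tested were higher, among them Ppara (5.10), a nuclear receptor of lipid metabolism, Acsl1 (3.004) and Etfdh (2.45). Oxidative phosphorylation genes were higher in 20 of 24, led by Sdhb (1.77), Cox5a (1.53) and Cyc1 (1.45), and in 21 adjusted over the list alone. The median of that list was 0.80, and TMM scaling raised such differences by 0.45. Glycolysis genes were higher in 16 of 18, with Hk2 at 3.48, Pfkm at 3.20 and Ldhb at 2.86. Of 9 fetal or stress genes 6 were higher and 1 lower, with Xirp2 at 4.32 and Ankrd1 at 3.29. Camera adjusted p-values were 9.3e-10 for the sarcomere list, 1.03e-10 for fatty acid oxidation, 4.58e-05 for oxidative phosphorylation, 1.41e-05 for glycolysis and 0.0655 for fetal or stress genes. With an estimated correlation the adjusted p was 0.269, 0.208, 0.298, 0.265 and 0.298, so none of the calls held.

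Among acetyltransferases and deacetylases 9 of 24 genes were higher and 4 lower (camera adjusted p = 0.268). Hdac9, a class IIa deacetylase, was higher by 2.41 and Sirt3, a mitochondrial deacetylase, by 2.01, while the coactivator Ncoa3 was lower at -1.28. Of 17 transcription factors known to work with p300/CBP 9 were higher and 3 lower (camera adjusted p = 0.0529), led by Tbx5 (3.86), Gata4 (2.39) and Gata6 (2.08). The medians of these lists, 0.14 and 0.36, lay below the 0.45 by which TMM scaling raised such differences. Their numbers of higher and lower genes thus depend on the scaling. Hypoxia genes went both ways, with 5 of 8 higher and 3 lower (camera adjusted p = 0.268), Vegfa at 3.23, Bnip3 at 2.19 and Ndrg1 at -3.03.

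Stromal, immune and cycling genes were lower in cardiomyocyte-like cells. Extracellular matrix genes were lower in 16 of 18, with Fbn1 at -4.02, Col5a2 at -3.86 and Eln at -3.71. Interferon response genes were lower in 12 of 13 (Bst2 -4.60, Oasl2 -4.36, Ifi44 -3.94) and antigen presentation genes in 7 of 11 (Tap1 -3.93, H2-D1 -3.73, B2m -3.18). Proliferation genes were lower in 7 of 10 and higher in 1, with Cdk1 at -3.55 (-1.46 in library 1 alone), Tpx2 at -3.40 and Top2a at -2.99. In cardiomyocyte-like cells Cdk1 was at 0.22 and 0.05 CPM, Tpx2 at 0.54 and 0.31 CPM and Top2a at 0.51 and 0.68 CPM. These fold sizes thus rest on few counts. Apoptosis genes were lower in 6 of 11 (Casp8 -3.55, Bcl2 -2.98, Bbc3 -2.67) and immediate early genes in 7 of 12 (Egr1 -2.66, Ier2 -2.54, Junb -1.21). Of 6 cytokine and chemokine genes 2 were lower, Tgfb1 (-3.46) and Ccl2 (-3.11), the latter losing its call with the stricter cell filter. Camera adjusted p-values were 4.94e-08, 1.63e-05, 0.0206, 0.0469, 0.0192, 0.0655 and 0.258 in this order. With an estimated correlation the adjusted p was 0.179, 0.166, 0.203, 0.298, 0.265, 0.298 and 0.298. Except for oxidative phosphorylation, the counts of these lists adjusted over the list alone were those over all genes.

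In the other classes, each against the mean of the rest, extracellular matrix genes were higher in 16 of 18 in fibroblast-like cells (camera adjusted p = 1.28e-17), 13 of 18 in endocardial-like cells (1.2e-05) and 9 of 18 in pericyte-like cells (0.00125). Col1a1, Col1a2 and Col3a1 of the matrix list are also fibroblast markers, so the fibroblast-like count is no independent evidence. All 11 antigen presentation genes were higher in macrophage-like cells (camera adjusted p = 2.66e-13), with a median log2 difference of 5.42. Interferon response genes were higher in 11 of 13 in endothelial-like cells (0.00234) and 8 of 13 in macrophage-like cells (0.0384). Proliferation genes were higher in 6 of 10 in lymphatic endothelial-like cells, which rest on 51 and 183 cells (camera adjusted p = 4.84e-05). With an estimated correlation the adjusted p of these lists was 0.0936, 0.378, 0.765, 0.244, 0.259, 0.321 and 0.417. Counts higher over the list alone were the same except for 10 matrix genes in pericyte-like and 8 proliferation genes in lymphatic endothelial-like cells. Of 6 cytokine and chemokine genes 4 were higher in macrophage-like cells (camera adjusted p = 0.0016, with an estimated correlation 0.244), also over the list alone.

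Other lists were lower in these classes. Extracellular matrix genes were lower in 13 of 18 and higher in 1 in macrophage-like cells (camera adjusted p = 6.1e-05), and 14 were lower over the list alone. In endothelial-like cells 8 matrix genes were lower and 5 higher (0.595), and 8 and 6 over the list alone. The mean of the rest includes cardiomyocyte-like cells, so lists higher there may be lower elsewhere for that reason. Sarcomere genes were lower in 10 of 24 in fibroblast-like (camera adjusted p = 0.00571), 3 in endocardial-like (0.00486) and 4 in lymphatic endothelial-like cells (0.00029). Fatty acid oxidation genes were lower in 8 of 19 (0.0472), 5 of 19 (0.00417) and 8 of 19 (0.000454) in these classes in this order. Oxidative phosphorylation genes were lower in 12 of 24 in fibroblast-like (0.00571) and 5 in lymphatic endothelial-like cells (0.00096), and glycolysis (9 of 18, 0.0101) and proliferation genes (4 of 10, 0.0472) in fibroblast-like cells. Over the list alone the sarcomere counts were 17, 0 and 0, those of fatty acid oxidation 9, 7 and 12, those of oxidative phosphorylation 14 and 8, of glycolysis 10 and of proliferation 7. With an estimated correlation the adjusted p of the lists in this paragraph was at least 0.289.

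Within the group, the libraries differed in which cardiomyocyte-like clusters they held. Clusters 0 and 1 held 72.5% of the cardiomyocyte-like cells of library 1 (interval 71.5 to 73.5) and 15.2% of library 2 (13.7 to 16.7), and clusters 2 and 3 held 22.3% and 82.2%. Cluster 14, led by the atrial genes Nppa, Myl4, Sln and Myl7, held 5.12% and 2.66%. Nppa in this cluster was at 4324 CPM in library 1 and 300 CPM in library 2, where it had 61 cells at a median of 1274 UMIs. With no correction for library, a cluster mostly of 1 library may be that library and not a cell state.

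**Figure D3:**
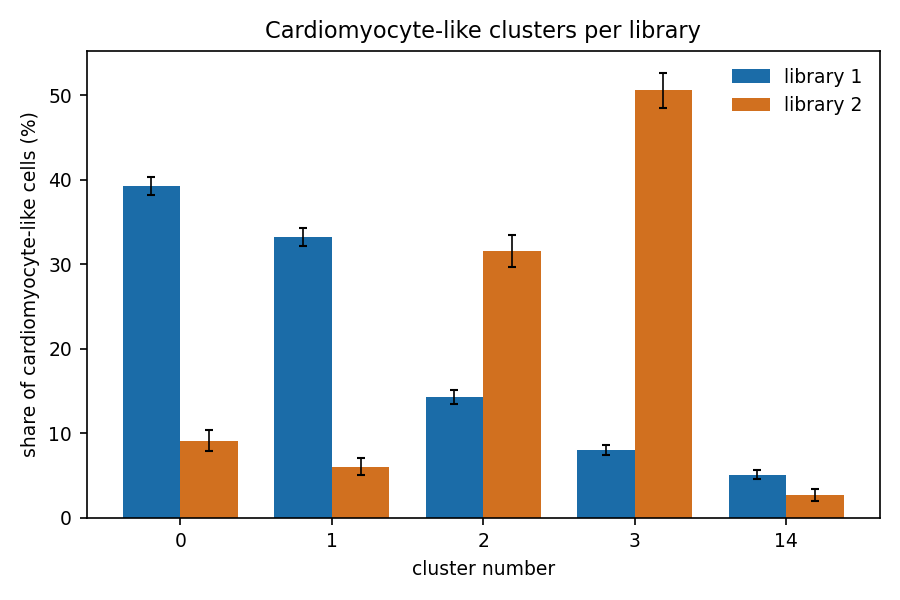
Share of cardiomyocyte-like cells (%, vertical axis from 0) in each of 5 clusters (horizontal axis) for library 1 and library 2. Error bars are 95% Clopper-Pearson intervals. Clusters 0 and 1 held 72.5% of library 1 and 15.2% of library 2.

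Calcium handling genes were left out of clustering and could be compared between these clusters, on 10 sums with 4 residual degrees of freedom. Genes that vary with them stayed in, so the clusters are not independent of the list. Median depth was 8284 UMIs in cluster 2 and 2432 in cluster 14. Of 14232 genes tested, 11 passed as higher and 558 as lower in cluster 2, and 3304 and 733 in cluster 14. Whether depth or gene length accounts for the differences below was not tested. In cluster 2, 12 of 26 members were higher than in the mean of the other clusters and 5 lower, with Pde4d and Cacna1c at 0.50 and Ryr2 at 0.42 (camera adjusted p = 0.00933). That mean includes cluster 14, where Pde4d and Cacna1c were low. Beside cluster 3 alone, Cacna1c was at 9586 and 12651 CPM in libraries 1 and 2, against 9587 and 12362 CPM. Pde4d was at 9379 and 9970 CPM against 6411 and 9158 CPM. Ryr2, at 16780.5 and 18623 CPM against 16875 and 20404 CPM, was not higher than in cluster 3. In cluster 14, 8 members were higher, Sln by 6.60 and Calm3 by 2.82, and 13 lower, Pde4d at -1.39 and Cacna1c at -1.30 (camera adjusted p = 0.0107). With an estimated correlation the adjusted p was 0.162 and 0.214. The medians were 0.15 and -0.31 while the means, pulled by Sln and Atp2b4, were -0.02 and 0.29. In cluster 1, 5 were higher and 4 lower (camera adjusted p = 0.185), and in cluster 3, 6 were higher and 5 lower (0.751). In cluster 0, 0 members passed the threshold in edgeR and 3 had an unadjusted p under 0.05. Adjusted over the list alone, 13 and 5 members passed in cluster 2, 8 and 14 in cluster 14, 8 and 5 in cluster 1, 9 and 7 in cluster 3 and 0 in cluster 0. In a contrast added after the data were seen, clusters 0 and 1 against clusters 2 and 3, Sorcs2 was higher by 0.47 and Jph2 lower at -0.33, and 24 of 26 members did not pass. Adjusted over the list alone 2 were higher and 5 lower. There Ep300 differed by -0.07 (SE 0.08, edgeR adjusted p = 0.794) and Crebbp by -0.04 (SE 0.07, edgeR adjusted p = 0.909).

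Within cardiomyocyte-like cells the calcium handling list had a small median difference between the libraries, with members going both ways. Of 26 members, 15 were at a higher level in library 2 and 11 in library 1. Its median log2 ratio of library 2 over library 1 was 0.03 (counting interval 0.02 to 0.04). It was at percentile 76.5 of random lists drawn by rank, 43.8 of lists drawn from the genes nearest in expression and 60.4 with gene length matched as well. Itpr2 (0.88), Slc8a1 (0.53), Cacna1c (0.46) and Ryr2 (0.30) were at a higher level in library 2. Itpr2 was at 450 CPM in library 2 cells with Xist alone and 142 CPM in those with Y-linked counts alone, against 145 CPM in library 1. Sln (-6.01), Hrc (-1.20), Sorcs2 (-0.87), S100a1 (-0.79), Pln (-0.50) and Atp2a2 (-0.25) were at a higher level in library 1. Mean levels were 17344 ± 2566 CPM for Ryr2, 10581 ± 2379 CPM for Cacna1c, 2691 ± 648 CPM for Pln and 36.3 ± 13.7 CPM for S100a1 (SD, n = 2). These values have no replicate check, and different clusters hold most of the class in the libraries.

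Other lists stood further apart between the libraries in cardiomyocyte-like cells. Median log2 ratios of library 2 over library 1 were -0.83 for fetal or stress genes, -0.51 for oxidative phosphorylation, -0.39 for sarcomere genes and -0.35 for fatty acid oxidation, each at percentile 0 of 10000 random lists. Glycolysis stood at -0.26 (percentile 0.4), apoptosis at -0.43 (2.61), hypoxia at -0.38 (5.08) and immediate early genes at -0.31 (13.5). Extracellular matrix genes stood at 0.23 (99.9), proliferation at 0.21 (98.0), antigen presentation at 0.08 (90.7), interferon response at 0.04 (89.7), p300/CBP partner factors at 0.05 (50.8) and acetyltransferases and deacetylases at 0.03 (46.1). With gene length matched as well, glycolysis was at percentile 14.5, immediate early genes at 66.5 and antigen presentation at 97.4. With library 2 restricted to cells with Xist and no Y counts, fatty acid oxidation stood at -0.02, immediate early genes at 0.16, extracellular matrix genes at 0.46, proliferation at 0.39, hypoxia at -0.67, interferon response at 0.20, antigen presentation at 0.04, partner factors at 0.01 and acetyltransferases and deacetylases at 0.00. Without cluster 14, matrix genes stood at 0.59, interferon response at 0.47, antigen presentation at 0.52 and immediate early genes at -0.18. Because the class lies in different clusters in each library, values within clusters 2 and 3 differed from these. There extracellular matrix genes stood at 1.19 and 0.97, antigen presentation, on 4 genes, at 1.16 and 1.00, oxidative phosphorylation at -0.30 and -0.23, fetal or stress genes at -0.53 and -1.37, immediate early genes at -0.46 (percentile 2.85) and -0.84 (0), and calcium handling at 0.09 and -0.08. Matrix genes were also at a higher level in library 2 outside this class, with medians of 0.87 in endothelial-like, 0.38 in fibroblast-like and 0.70 in macrophage-like cells, beside the larger share of fibroblast-like cells there. Mitochondrially encoded transcripts of the whole class were at 3903 CPM in library 1 and 1549 CPM in library 2. Cytokine genes had too few counts.

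**Figure D4:**
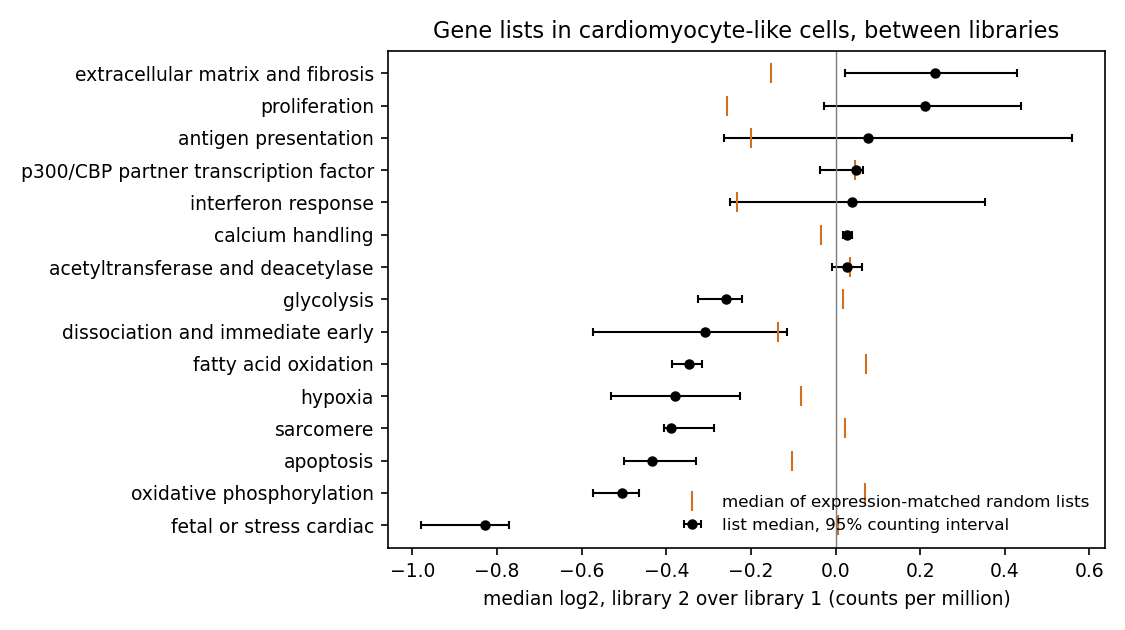
Median log2 ratio of library 2 over library 1 (horizontal axis, CPM scale) for 15 gene lists in cardiomyocyte-like cells. Points are list medians with 95% counting intervals and orange marks the median of expression-matched random lists. Fetal or stress genes were lowest at -0.83.

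Of 10924 genes compared in cardiomyocyte-like cells, 80 were over 2-fold higher in library 2 and 336 over 2-fold higher in library 1. Those highest in library 1 were Alb, Sln, Nppa, Myl7, Snx17, Fcrla, Hist1h1e, Fah, Sbk3 and Prkcq. The albumin gene Alb had 463 UMIs in library 1 and 0 in library 2, which allows up to 0.156 CPM there. Nppa, atrial natriuretic peptide, was at 184 and 6.71 CPM, and Myl7, the atrial myosin light chain, at 25.1 and 1.20 CPM. Of the 8243 Nppa UMIs of library 1, 6797 lay in the 406 cells of cluster 14. Without that cluster the log2 ratio was -3.22 for Nppa (-4.77 with it), -2.36 for Myl7 (-4.36), -4.30 for Sln (-6.01) and -1.37 for Sbk3 (-2.64). Those highest in library 2 were 2610035D17Rik, D7Ertd443e, Pde10a, Gpm6a, Fam155a, Nr4a1, Shtn1, Sik1, Nipal2 and Glis3, with log2 ratios from 1.80 to 2.62. Fam155a did not hold its direction when library 2 was restricted to cells with Xist and no Y counts, where it stood at -0.67, and it was at 0.34 without cluster 14. With only those Xist-bearing cells of library 2, Shtn1 (0.80), Nipal2 (0.57) and Glis3 (0.70) fell below 2-fold.

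Of the 10 genes highest in library 1, those higher in cardiomyocyte-like cells than in the mean of the other classes numbered 7 in fibroblast-like, 10 in endothelial-like and 10 in macrophage-like cells. In fibroblast-like cells the genes highest in library 1 included Nppa, Tcap, Hrc, Snx17, Rnf207, Kcnj3, Tnnc1, Cox7a1 and Asb11, in endothelial-like cells Tcap, Kcnj3, Synpo2, Angpt1, Dmpk, Chrm2, Rbm20, Cdh2, Rbm24 and Kcnn2, and in macrophage-like cells Chrm2, Corin, Pln, Tnnt2, Kcnd2, Rbm20, Trdn, Cdh2, Cacnb2 and Fhl2. Cardiomyocyte marker transcripts were at 8677 CPM in macrophage-like cells of library 1 and 2732 CPM in library 2. In library 2 fibroblast-like cells had higher levels of Gpm6a, Rab6b, Thsd7b, Egr1, Postn, Cry1, Igf2, Kcnb2, Mthfd1l and Cmah. Postn, a matrix protein of activated fibroblasts, was at 55.4 and 233 CPM, and Igf2, a growth factor, at 12.1 and 48.3 CPM. Fibroblast-like cells too lay in different clusters, with 619 of 1121 in cluster 8 in library 1 and 1359 of 2477 in cluster 4 in library 2. Thsd7b and Kcnb2 were among the leading genes of cluster 11, which held 156 and 476 cells. Endothelial-like cells of library 2 had higher levels of 2610035D17Rik, Negr1, Zbtb7c, Col3a1, Igfbp5, Kcnc2, Myrip, D5Ertd615e, Pcdh9 and Ptprj. Macrophage-like cells of library 2 had higher levels of Pde7b, Pola1, Epb41l1, Xdh, Actg1, Dcn, Abcc3, Herc6, Pdgfc and Cadm1, by log2 ratios of 1.08 to 1.45. With library 2 restricted to cells with Xist and no Y counts, Actg1 (0.66) and Herc6 (0.64) fell below 2-fold. Dcn here and Col3a1 in endothelial-like cells encode matrix proteins, and the matrix list was at a higher level in library 2 in each of these classes.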

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

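Liver and Y-linked transcripts appeared in cells of library 1 that no comparison between classes used, above the limit that a count of 0 allows. Both tests in this part were chosen after the values were seen. In cluster 21 (80 cells, with Mug1, Cps1, Serpina3k, Ttr and Apoa1 among its leading genes) a set of 21 liver transcripts was at 66292 CPM, and in cluster 16 (192 cells) it was at 21123 CPM. In cardiomyocyte-like cells the same set was at 39.0 CPM in library 1 and 1.72 CPM in library 2. Other named classes of library 1 also had it, from 34.3 CPM in lymphatic endothelial-like cells to 270 CPM in endocardial-like and 1216 CPM in smooth muscle-like cells, where 51.8% of 56 cells had a liver UMI. Y-linked transcripts were at 122 CPM in cluster 21, from 24 UMIs in 20% of its cells, against 0.782 CPM in cardiomyocyte-like cells of library 1, where 95.2% of cells had an Xist UMI.

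In cluster 21 the most abundant of these were Alb at 15147 CPM, Apoa2 at 7176 CPM and Mup3 at 4753 CPM. In cardiomyocyte-like cells 13 of the 21 genes were over 1 CPM in library 1 and 1 in library 2. The tables argue against free liver RNA spread evenly over droplets as the source in cluster 21. Its cells held 162 liver UMIs each, 668 times the 0.243 per cell of the other kept cells of library 1 outside cluster 16 (interval 641 to 695). Liver RNA in clumps or debris stays open. The Y-linked level in cluster 21 was 157 times that of the cardiomyocyte-like cells of the library (interval 100 to 233). This goes with liver material of another, male animal than the source of those heart cells. The enrichment of CD45-positive cells in the protocol should remove liver cells, but also cardiomyocyte-like cells, which were 66.4% of library 1. Xist had a UMI in 35.0% of the cells of cluster 21, which may be free RNA or cells of both sexes. Cluster 16 had a median of 714 UMIs and 4803 liver UMIs in all, and whether these, or the liver UMIs of smooth muscle-like cells, lie in cells or in free RNA was not tested. The liver genes were listed after the data were seen, and no biological explanation was tested, since the labels give 1 group.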

How the results depend on the processing

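Of 1534 values of results recomputed under an alternative, leaving aside left-out libraries, 1414 counted as the same, 7 lost and 6 gained a call and 104 moved. Another 3 changed sign where the threshold was passed or the counting interval left out 0. Values counted as the same if they kept their direction and side of the threshold or moved by less than their spread or counting interval. So did sign changes with no call on either side, and numbers of genes within a fixed ratio of the main number. Without a filter on low counts, the number of genes higher in cardiomyocyte-like cells than in the mean of the other classes was 3983. More genes were tested (23424), and scaling on them raised log2 differences of the 12399 genes by a median of 0.21, with 2664 of these higher and 2366 lower. With the scaling factors of the filtered genes the numbers were 3294 and 2969, so both contribute. Crebbp in those cells passed the threshold at 0.43 without that filter, 0.20 with DESeq2, 0.34 at resolution 0.5 and 0.33 with list genes kept in clustering, with adjusted p-values over its alternatives from 0.00629 to 0.39. With the scaling kept and no filter it stood at 0.21 and did not pass, so the first of these rests on the scaling, and the cause of the others was not tested. With no replicate block there were 2178 genes higher in cardiomyocyte-like cells than in the mean of the other classes and 2658 genes lower in cardiomyocyte-like cells than in the mean of the other classes, and the Sln and S100a1 calls were lost. Without the atrial-gene cluster, an alternative added later, Sln stood at -0.56. The share of smooth muscle-like cells was 1.09% with the stricter cell filter, against a mean of 0.364%. Ep300 was at 119 CPM in cardiomyocyte-like cells after thinning, and the level of Ep300 in macrophage-like cells, mean CPM, was 252 at resolution 0.5, 259 at resolution 2, 222 with doublets kept, 264 with the stricter filter and 303 after thinning. The value of the calcium handling list in cardiomyocyte-like cells, median log2 library 2 over library 1, was 0.105 with TMM, 0.0571 after thinning, 0.0140 without the atrial-gene cluster and -0.0400 with only library 2 cells with Xist and no Y counts. In that last setting, added later, Fam155a stood at -0.67. The causes of these last shifts were not tested. Leaving out a library gave values of 1.98 to 3.07 for the calcium handling median, with no test. Depth limits the small classes, such as the 22 smooth muscle-like cells of library 2, and counts of 0.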

Other observations

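The comparison within library 2, the restriction of library 2 to cells with Xist and the test of scaling were chosen after their result was seen. Library 2 held cells of both sexes. Of its 2289 cardiomyocyte-like cells, 34.3% had Xist and no Y-linked UMI, 46.3% had Y-linked and no Xist UMI and 15.6% had both, whereas 94.8% of those of library 1 had Xist and no Y-linked UMI. Library 2 thus held cells of at least 2 animals. GFP had a UMI in 20.3% of its cells with Xist alone (interval 17.5 to 23.2) and 22.3% of its cells with Y-linked counts alone (19.8 to 24.9). Within library 2, with no replicate check, 46 of 7032 genes were over 2-fold higher in cells with Xist alone and 16 in cells with Y-linked counts alone. Among them, Angptl4, an inhibitor of lipoprotein lipase, stood at a log2 ratio of -2.82 (Y-linked over Xist), and the insulin receptor substrate Irs2 was at 107 CPM in cells with Xist and 32.9 CPM in cells with Y-linked counts. The calcium release channel Itpr2 was at 450 and 142 CPM, with library 1 at 145 CPM. The fatty acid oxidation list, at -0.35 between the libraries, stood at -0.02 when library 2 was restricted to cells with Xist alone, and the sarcomere list at -0.40. Ep300 was at 105 and 121 CPM and Crebbp at 462 and 473 CPM. Sex and animal cannot be separated here.

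The first pattern is that cardiomyocyte-like cells of library 1 lay mostly in clusters 0 and 1 and those of library 2 in clusters 2 and 3. Sex alone does not account for it, since of the library 2 cells with Xist and no Y-linked counts 16.1% lay in clusters 0 and 1 (interval 13.6 to 18.8). Depth alone does not either, since among cells of 4000 to 6000 UMIs the shares were 75.9% in library 1 and 23.2% in library 2, a difference of 52.7 percentage points. Tissue from the left ventricle or septum in one library remains possible, as Tbx5, a factor richer in left ventricle, was 0.43 higher in clusters 0 and 1 (SE 0.09, edgeR adjusted p = 0.00482), between the bounds set for a decision. Animal and preparation stay open, and no biological explanation was tested.

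The next pattern is the lower level of sarcomere, fetal or stress, fatty acid oxidation and oxidative phosphorylation genes in cardiomyocyte-like cells of library 2. Gene length tracked the libraries, with a median log2 ratio of -0.41 in the shortest 25% of genes (up to 10674 bases) and 0.12 in the longest 25% (from 63037 bases). Among 10000 random lists matched on expression and length, the 75 genes of the 4 lists, at a median of -0.40, were at percentile 0, the random median being -0.16. Length may account for part of the difference. Whether it accounts for all of it is not decided, since the 4 lists were picked for low values in these same ratios. Random lists also drew genes singly, although members of such lists vary together. Oxidative phosphorylation alone was at percentile 1.7. With library 2 restricted to cells with Xist alone, fatty acid oxidation stood at -0.02, so for this list sex and animal stay open, while sarcomere genes stood at -0.40, fetal or stress genes at -1.21 and oxidative phosphorylation at -0.61. TMM scaling takes a log2 shift of -0.08 off all genes of the class alike. The median was then -0.32 (interval -0.34 to -0.30), so this scaling does not account for the lower level. A larger share of cytoplasmic RNA in library 1, animal and tissue region stay open. Over all barcodes, the median mitochondrial share (0.338% in library 1, 0.229% in library 2) went with a larger cytoplasmic share. Malat1, a nuclear RNA, at 5.58% and 3.73% of counts went the other way.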
